A study of Mus musculus with 8 samples.

How the data were processed

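Total RNA from 8 mouse cell cultures was measured on 8 Affymetrix arrays, 1 array per culture. Per the labels, biotin-labelled cRNA was made from 3 ug of total RNA extracted with Trizol. The deposited values are on a log2 scale, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, which corrects background, normalises between arrays and summarises the probes of a probe set. The version and settings of RMA are not given in the sources used here. The deposited table held 45101 probe sets, of which 64 were Affymetrix control probe sets and were left out of all comparisons. Of the other 45037 probe sets, 34945 named 1 gene in the platform annotation, 932 named several and 9160 had no gene name in the table used here. Entrez identifiers of 34741 of the single-gene probe sets were found in a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols were changed by it. That table was used only for gene names, chromosomes and the order of genes along them. No genome build is named with the arrays, so no coordinates are given. No other columns of values were present (0 unused).

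Each gene was represented by the probe set with the highest mean over the 8 arrays among those naming that gene alone, which gave 18193 genes, 9010 of them with more than 1 probe set. Samples were grouped from their titles into MEF (2 arrays), ES (2 arrays), 4F iPS (2 arrays) and 3F iPS (2 arrays). Linear models were fitted to the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 8 arrays and 4 groups in 1 fit and 4 residual degrees of freedom. The contrasts were iPS (the mean of both iPS groups) minus MEF, ES minus MEF, iPS minus ES, and 3F iPS minus 4F iPS. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its difference at least 2-fold (1 on the log2 scale). No filter on dim genes was applied. Adjusted p-values below are two-sided and from limma. The number of arrays limits the precision.

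Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, two-sided and adjusted over the 28 lists of a comparison, and again with the correlation estimated per list and with fry. The 28 lists held 542 members, of which 493 were measured. They cover pluripotency, the reprogramming factors, the formative or primed epiblast, the 2-cell embryo, markers of fibroblasts, epithelium, primitive endoderm, trophectoderm, mesoderm, neural cells, the germ line, macrophages, endothelium, skeletal muscle and adipocytes, imprinted genes, Hox genes, DNA methylation and chromatin factors, the cell cycle, senescence and cell cycle arrest, Myc targets, glycolysis, cholesterol synthesis, the serum response, the interferon response, antigen presentation, oxidative stress and metal response, and sex-linked genes. Some genes are in more than 1 list.

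The groups, contrasts, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where a later choice is stated. The rule takes, in each tested contrast, the 5 highest and 5 lowest differences among called genes whose groups do not overlap on any array, passing over symbols that begin with Gm or LOC and a digit, that end in Rik, or that are clone or accession numbers. From each list it takes up to 3 called members with the largest difference in the direction most called members take and 1 in the other direction, or the member with the smallest p where none was called. It takes Pou5f1, Sox2, Klf4, Myc, Nanog, Thy1, Cdh1, Xist and Meg3 in every contrast, and all called genes where a contrast calls 10 or fewer. For pairs of single arrays it takes the 5 highest and 5 lowest differences among genes with a mean of at least 6 and the 2 members of each list with the largest difference. The text gives part of the genes so chosen.

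Arrays were compared pairwise by Pearson's r across genes, and genes are not independent replicates. For overlaps of contrasts that share arrays, 20 simulations without any group difference gave the values without effects, and the product of the call counts divided by the genes tested gave that of independent lists. The pairs of MEF media and of ES lines have 1 array each, so no test was made. Their list medians were ranked among those of 10000 random lists of the same size and matched expression. The alternatives were an intensity trend or robust variance in eBayes, array weights, only the compared groups in the fit, quantile normalisation, subtraction of each array's median, a filter for a log2 value of at least 6 on at least 2 arrays, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at, _s_at or _a_at, no fold minimum, and leaving out each array in turn.

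The procedure was tested on simulated data with 18193 genes and 200 changed genes. In the iPS minus ES contrast it recovered 94 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3, with 3 false calls and 0 wrong signs. In the 3F minus 4F contrast it recovered 89 of 100 and 99 of 100, with 2 false calls and 0 wrong signs. Of 10 simulated lists of 25 genes shifted by 0.5, 10 were recovered in either contrast, and 0 of 90 lists without a shift were called. The simulated genes varied independently of one another. The list simulation therefore does not show how often lists of correlated genes are called without a shift.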

Results

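Gene expression was measured in mouse embryonic fibroblasts (MEF), in embryonic stem (ES) cell lines and in induced pluripotent stem (iPS) cell lines derived from MEF. The 2 MEF arrays came from embryos of day 13.5 of the strain OG2/Rosa26, 1 grown in serum-free and 1 in serum-containing medium. The 2 ES arrays were of the lines CGR8 and R1, made from day 3.5 embryos of the strain 129sv. Of the 4 iPS lines, all of the OG2/Rosa26 strain, S2C12 and S2C16 were induced with Oct4 (Pou5f1), Sox2, Klf4 and c-Myc (4F), and S53C1 and S53C5 without c-Myc (3F). The sample titles call all 4 iPS lines serum-free. The arrays were alike in overall signal, with medians over all probe sets between 5.60 and 5.66 on the log2 scale, and 56.3% to 57.7% of the 18193 genes had a value of at least 6. Differences between groups are given on the log2 scale ± SE of the limma fit, from 4 iPS, 2 ES and 2 MEF arrays. Each array is of a different line or medium and none was repeated, so p-values measure only the spread between these samples. In each of the MEF and ES pairs that spread includes a difference of medium or of line. Strain goes with the ES group and cannot be told apart from it. The labels give the sex of no sample, so sex may also differ between groups.

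The 4 iPS lines lay much closer to ES than to MEF. Across genes, Pearson's r between an iPS line and an ES line averaged 0.969 (0.966 to 0.972 over 8 pairs, SD 0.00226), and between an iPS line and a MEF array 0.842 (0.820 to 0.863 over 8 pairs, SD 0.0146). The iPS lines were nearer to one another, at a mean r of 0.993 (0.990 to 0.995 over 6 pairs), and the ES lines had an r of 0.992. An iPS line and an ES line differed by at least 2-fold in 1266 to 1575 genes, against 47 to 278 genes between iPS lines, 167 between the ES lines and 4819 to 5563 between an iPS line and a MEF array. The MEF arrays in the different media differed in 1276 genes.

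The first comparison asked how the iPS lines differ from the MEF arrays, which have the same strain label. Pluripotency genes rose and genes of fibroblast identity fell. Nanog, a transcription factor of the pluripotent state, rose by 8.43 ± 0.24 (adjusted p = 1.24e-06), Dppa5a by 8.86 ± 0.10 (adjusted p = 1.1e-07) and Tdgf1, a Nodal co-receptor, by 8.53 ± 0.16 (adjusted p = 3.61e-07). Cdh1, which encodes E-cadherin, rose by 8.16 ± 0.11 (adjusted p = 1.63e-07). The chemokine gene Cxcl12 fell by 7.67 ± 0.19 (adjusted p = 8.19e-07), Lrrc17 fell by 7.30 ± 0.20, the matrix proteoglycan gene Ogn fell by 7.02 ± 0.43, the fibrillin gene Fbn2 fell by 6.95 ± 0.22 and Aspn fell by 6.73 ± 0.43 (adjusted p at most 2.38e-05). In all, 4934 genes were called, 2586 higher and 2348 lower in iPS, of which 334 and 444 by at least 8-fold.

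**Figure D1:**
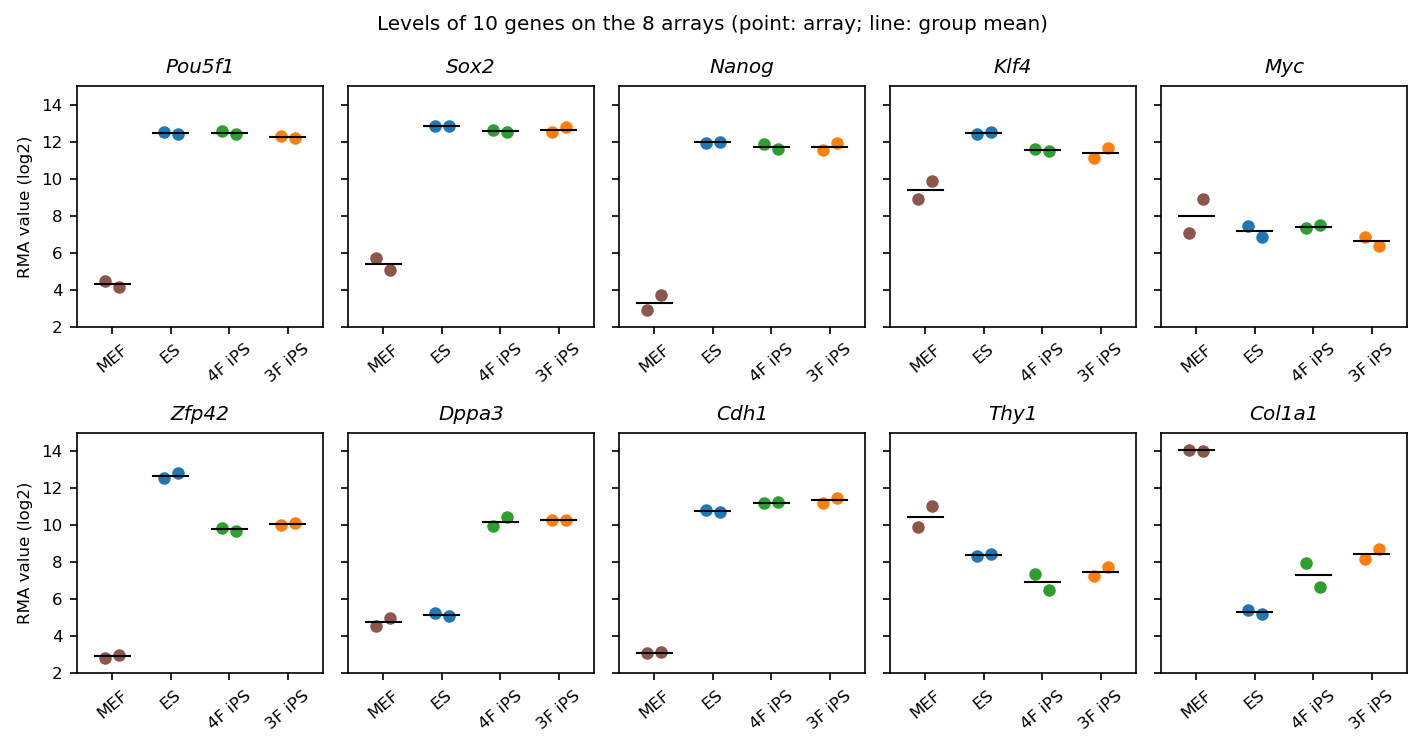
Log2 RMA values of 10 genes on each array (points, with the group mean as a line) in MEF, ES, 4F iPS and 3F iPS cells. Pou5f1, Sox2 and Nanog sat at similar levels in ES and iPS cells, Zfp42 averaged 12.66 in ES and 9.91 in iPS cells, and Dppa3 averaged 10.22 in iPS cells and 5.16 in ES cells.

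All 36 measured pluripotency genes rose (median 6.13, camera adjusted p = 1.77e-24, and adjusted p = 0.00891 with an estimated correlation). Of the 4 reprogramming factors 3 rose, Pou5f1 by 8.06 ± 0.12 (adjusted p = 2.27e-07), Sox2 by 7.22 ± 0.19 (adjusted p = 1.05e-06) and Klf4 by 2.07 ± 0.27 (adjusted p = 0.000653). That list was called (median 4.64, adjusted p = 0.0216, and adjusted p = 0.193 with an estimated correlation). Myc was not called at -0.95 ± 0.48 (adjusted p = 0.147), but was called without the serum-free MEF array at -1.88 (adjusted p = 0.000583). The arrays do not separate the cells' own factor transcripts from any transgene transcripts.

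Of 35 fibroblast genes 33 fell and 0 rose, and 35 fell when p was adjusted over the list alone (median -4.82, camera adjusted p = 3.44e-17, and adjusted p = 0.182 with an estimated correlation). The collagen genes Col3a1 and Col1a1 fell by 6.55 ± 0.39 and fell by 6.17 ± 0.35, and the matricellular gene Postn fell by 6.24 ± 0.32. Thy1, a surface marker of fibroblasts, fell by 3.25 ± 0.36 (adjusted p = 0.000272). Of 21 epithelial genes 18 rose (median 2.62, camera adjusted p = 2.39e-09, and adjusted p = 0.0347 with an estimated correlation), among them the splicing factor gene Esrp1 by 5.76 ± 0.20 and the adhesion gene Epcam by 5.70 ± 0.16. Of 33 Hox genes, which set position along the body axis, 22 fell and 0 rose (median -1.70, camera adjusted p = 1.1e-10, and adjusted p = 0.0814 with an estimated correlation). Hoxc8 fell by 4.88 ± 0.36 and Hoxd13 fell by 4.43 ± 0.20.

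Many genes of the cell cycle, Myc target, chromatin, germ line and glycolysis lists were higher in iPS cells. Of 28 cell cycle genes 26 rose (median 2.06, camera adjusted p = 3.04e-14, and adjusted p = 0.0347 with an estimated correlation), with the replication licensing genes Cdc6, Cdt1 and Mcm3 up by 3.75 ± 0.22, 3.32 ± 0.15 and 3.23 ± 0.12. Of 25 Myc targets 23 rose (median 1.63, camera adjusted p = 2.46e-08, and adjusted p = 0.313 with an estimated correlation), including Dkc1, which acts in ribosome synthesis and telomerase, by 3.18 ± 0.17. Of 22 genes of DNA methylation and chromatin 18 rose and 1 fell (median 2.06, camera adjusted p = 1.33e-08, and adjusted p = 0.0783 with an estimated correlation). In that list Dnmt3l and the methyltransferase Dnmt3b rose by 6.37 ± 0.23 and 5.41 ± 0.24, Tet1, which oxidises methylated cytosine, rose by 4.85 ± 0.27, and the Polycomb gene Bmi1 fell by 2.49 ± 0.13. Of 18 germ line genes 15 rose (median 4.20, camera adjusted p = 5.12e-09, and adjusted p = 0.0995 with an estimated correlation), with Tex19.1 up by 6.30 ± 0.12, Rnf17 by 5.88 ± 0.14 and Mael by 5.14 ± 0.18. Of 16 glycolysis genes 12 rose (median 1.40 and, without the serum-free MEF array, 0.86, camera adjusted p = 0.000488, and adjusted p = 0.400 with an estimated correlation), led by the glucose transporter gene Slc2a3 at 5.69 ± 0.10.

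Some genes of the arrest, serum response, interferon and antigen presentation lists fell. Of 17 senescence and arrest genes 11 fell and 1 rose (median -1.83 and, without the serum-free MEF array, -1.04, camera adjusted p = 0.00298, and adjusted p = 0.222 with an estimated correlation), with the Cdk inhibitor gene Cdkn2b down to 6.88 ± 0.25 (SD) in iPS from 10.28 ± 0.68 in MEF and Gadd45a up by 1.91 ± 0.30. Of 27 serum response genes 16 fell (median -1.79, camera adjusted p = 0.00165, and adjusted p = 0.499 with an estimated correlation). The smooth muscle genes Myl9 and Acta2 fell by 4.23 ± 0.53 and fell by 3.84 ± 0.49. Of 21 interferon response genes 10 fell, or 11 adjusted over the list alone, and 1 rose (median -1.26, camera adjusted p = 0.00331, and adjusted p = 0.553 with an estimated correlation). Ifit2 fell by 3.25 ± 0.39, and Oas1a rose by 1.85 ± 0.25. Of 10 antigen presentation genes 3 fell (median -0.82, adjusted p = 0.0173, and adjusted p = 0.268 with an estimated correlation), with B2m, the light chain of MHC class I, down by -3.73 ± 0.26. Of 30 imprinted genes 15 fell and 5 rose (median -1.48, adjusted p = 0.0216, and adjusted p = 0.516 with an estimated correlation), with the growth factor gene Igf2 at -5.08 ± 0.22 and Phlda2 at 4.31 ± 0.27. Meg3, an imprinted non-coding RNA, fell by 2.29 ± 0.33 (adjusted p = 0.001). Without the serum-free MEF array the medians of the interferon, antigen presentation and imprinted lists were -0.42, -0.44 and -0.60, and none of these lists was called (adjusted p = 0.0608 each). Without the serum MEF array the interferon median was -2.13.

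Among the other lists, 5 of 15 genes of the formative or primed epiblast rose and 1 fell (median 0.58, adjusted p = 0.0216, and adjusted p = 0.193 with an estimated correlation), and this call was lost without the serum MEF array (adjusted p = 0.0537). Otx2 rose by 3.99 ± 0.14 and Sox4 fell by 3.38 ± 0.24. Of 8 genes of the 2-cell embryo 4 rose (median 1.82, adjusted p = 0.0216, and adjusted p = 0.401 with an estimated correlation), among them Pramel6 by 3.67 ± 0.54. Of 14 trophectoderm genes 5 rose (median 0.39, adjusted p = 0.0335, and adjusted p = 0.306 with an estimated correlation), with Tfap2c up by 7.10 ± 0.15, and the call was lost without the serum-free MEF array (adjusted p = 0.0663). Of 13 macrophage genes 4 fell and 2 rose (median -0.39, adjusted p = 0.0359, and adjusted p = 0.3 with an estimated correlation), with Lyz2 at -2.30 ± 0.24 and Laptm5 at 4.48 ± 0.20, and the call was lost without either MEF array (adjusted p = 0.0608 and 0.0559). Of 12 oxidative stress and metal response genes 5 rose, and 1 also fell when adjusted over the list alone (median 0.96, adjusted p = 0.048, and adjusted p = 0.228 with an estimated correlation). Gsta4 rose by 3.56 ± 0.28, and the call of this list was lost without any 1 of the ES or iPS arrays (adjusted p = 0.0504 to 0.0590).

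Lists not called were primitive endoderm (3 of 19 up, 5 down, adjusted p = 0.856), mesoderm (1 of 13 down, adjusted p = 0.540), neural (2 of 14 up, 3 down, adjusted p = 0.239), endothelial (3 of 12 up, adjusted p = 0.540), skeletal muscle (3 of 13 up, 1 down, adjusted p = 0.852), adipocyte (2 of 7 down, adjusted p = 0.0531), cholesterol synthesis (2 of 17 down, adjusted p = 0.625) and sex-linked genes (3 of 6 down, adjusted p = 0.189). The primitive endoderm list had a median of 0.10 but a mean of -0.22 and a downward test, and the skeletal muscle list a median of -0.02 but a mean of 0.29 and an upward test. The Y-linked gene Eif2s3y was lower in iPS by 4.02 ± 0.25. Xist, the RNA of the inactive X chromosome, was lower by 2.15 ± 0.34, or by 4.36 ± 0.50 by another of its probe sets. Because the sex of the samples is not labelled, these differences cannot be read as a change during reprogramming. Of the other bright probe sets of called genes, 98.0% had the sign of the one used, and 10 were at least 2-fold the other way.

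ES cells were compared with MEF as the reference for the pluripotent state. Zfp42 (Rex1), a marker of ES cells, was higher in ES by 9.75 ± 0.14 (adjusted p = 3.07e-07), Tdgf1 by 9.35 ± 0.18, Dppa5a by 8.66 ± 0.11, Nanog by 8.65 ± 0.28 and Dppa2 by 8.18 ± 0.19 (adjusted p at most 2.78e-06). Col3a1 was lower at -10.11 ± 0.45, the cadherin gene Cdh11 at -9.56 ± 0.45, Col5a2 at -9.09 ± 0.44, Col1a1 at -8.73 ± 0.40 and Lox, a collagen crosslinking enzyme, at -8.57 ± 0.58 (adjusted p at most 4.1e-05). Pou5f1, Sox2 and Klf4 were higher by 8.16 ± 0.14, 7.45 ± 0.22 and 3.05 ± 0.31, and Cdh1 by 7.65 ± 0.13. Thy1 was lower at -2.05 ± 0.41 (adjusted p = 0.00574). Myc was not called at -0.82 ± 0.55 (adjusted p = 0.282), but was called without the serum-free MEF array at -1.75 (adjusted p = 0.00152). In all, 4926 genes were called, 2741 higher and 2185 lower in ES cells.

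In ES cells 35 of 36 pluripotency genes were higher and 0 lower (median 6.14, camera adjusted p = 5.63e-25, and adjusted p = 0.00856 with an estimated correlation), and 33 of 35 fibroblast genes were lower (median -4.93, adjusted p = 3.36e-18, and adjusted p = 0.167 with an estimated correlation). Higher too were 25 of 28 cell cycle genes (adjusted p = 1.43e-13, and adjusted p = 0.0398 with an estimated correlation) and 14 of 18 germ line genes (adjusted p = 2.66e-08, and adjusted p = 0.115 with an estimated correlation). Of the chromatin genes 17 of 22 were higher and 1 lower (adjusted p = 1.15e-08, and adjusted p = 0.0748 with an estimated correlation). Of 21 epithelial genes 13 were higher (adjusted p = 8.72e-06, and adjusted p = 0.0748 with an estimated correlation), and of 25 Myc targets 16 (adjusted p = 4.66e-06, and adjusted p = 0.430 with an estimated correlation). Of 33 Hox genes 22 were lower and 1, Hoxc13, higher by 2.22 ± 0.14 (adjusted p = 6.3e-10, and adjusted p = 0.0928 with an estimated correlation). Of 27 serum response genes 20 were lower, or 21 adjusted over the list alone, and 1 higher (adjusted p = 1.41e-06, and adjusted p = 0.395 with an estimated correlation). Thbs1, a matrix glycoprotein gene of that list, was lower at -7.49 ± 0.94 and Myl9 at -6.51 ± 0.62.

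Of 30 imprinted genes 14 were lower in ES than in MEF and 2 higher (adjusted p = 0.00136, and adjusted p = 0.430 with an estimated correlation), with Plagl1, a zinc finger gene, at -8.35 ± 0.60 and Igf2 at -7.26 ± 0.26. Of 17 senescence and arrest genes 9 were lower, or 11 adjusted over the list alone (adjusted p = 0.00354, and adjusted p = 0.235 with an estimated correlation). Of 21 interferon response genes 8 were lower, or 12 adjusted over the list alone, and 1 higher (median -1.36 and, without the serum-free MEF array, -0.48, or without the serum MEF array, -2.14, adjusted p = 0.00218, and adjusted p = 0.582 with an estimated correlation). Of 10 antigen presentation genes 5 were lower (median -1.04 and, without the serum-free MEF array, -0.65, adjusted p = 0.0158, and adjusted p = 0.3 with an estimated correlation). Of 16 glycolysis genes 8 were higher (median 1.16, or 0.56 without the serum-free and 1.76 without the serum MEF array, adjusted p = 0.00539, and adjusted p = 0.526 with an estimated correlation). Of 17 cholesterol synthesis genes 4 were lower (median -0.69, or -1.12 without CGR8, adjusted p = 0.00356, and adjusted p = 0.582 with an estimated correlation), and the call was lost without R1 (median -0.21, adjusted p = 0.112).

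The reprogramming factors were called (3 of 4 higher, adjusted p = 0.0108, and adjusted p = 0.171 with an estimated correlation). Macrophage genes were called lower (4 of 13 lower and 2 higher, adjusted p = 0.0254, and adjusted p = 0.3 with an estimated correlation), but not without CGR8 (adjusted p = 0.0545). Formative or primed genes were called higher (6 of 15 higher and 1 lower, median 0.43 and, without the serum-free MEF array, 0.79, adjusted p = 0.0487, and adjusted p = 0.235 with an estimated correlation). That call was lost without CGR8 (median 0.24, adjusted p = 0.0559), R1 (adjusted p = 0.0641), the serum MEF array (adjusted p = 0.0914) or either 3F line (adjusted p = 0.0552). The other 10 lists, among them the 2-cell embryo (0 of 8, adjusted p = 0.933) and trophectoderm (2 of 14 higher and 3 lower, adjusted p = 0.933), were not called. Median, mean and test differed in sign in the 2-cell, trophectoderm, mesoderm and skeletal muscle lists.

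The same genes were largely called on the same side of MEF in iPS and in ES cells. There were 2032 genes higher in both and 1850 lower in both, against 389.6 and 282.0 for independent lists of these sizes, and 10 opposite against 664.3. Simulations without effects call almost no genes and gave 0 in each case, so they do not show how much overlap the shared arrays add. The contrasts share the MEF arrays, so part of the excess may come from them. With the MEF arrays split, a choice made after the data were seen, the serum-free array for iPS and the serum array for ES gave 1830 higher and 1654 lower in both, against 420.8 and 321.6 for independent lists. The other way round gave 1916 and 1690, against 409.1 and 311.6, and the 2 splits gave 55 and 42 opposite genes. The covariance of the log2 differences was 1.54, against 0.0261 in the simulations, and 1.43 and 1.47 with the arrays split. Each split contrast rests on 1 MEF array, assumed to vary like the other groups. Of the 2741 genes higher in ES than in MEF, 2032 (74.1%) were also called in iPS, and the median gene had gained 88.7% of the ES difference. Of the 2185 genes lower in ES, 1850 (84.7%) were also called, with a median of 95.7%. Of the same 2 sets, 313 (11.4%) and 170 (7.78%) were called in iPS against ES on the MEF side, and 74 and 76 beyond ES. Both sets were chosen by their call in ES against MEF, which favours large ES differences. Part of the shortfall and of the calls on the MEF side may come from that choice.

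**Figure D2:**
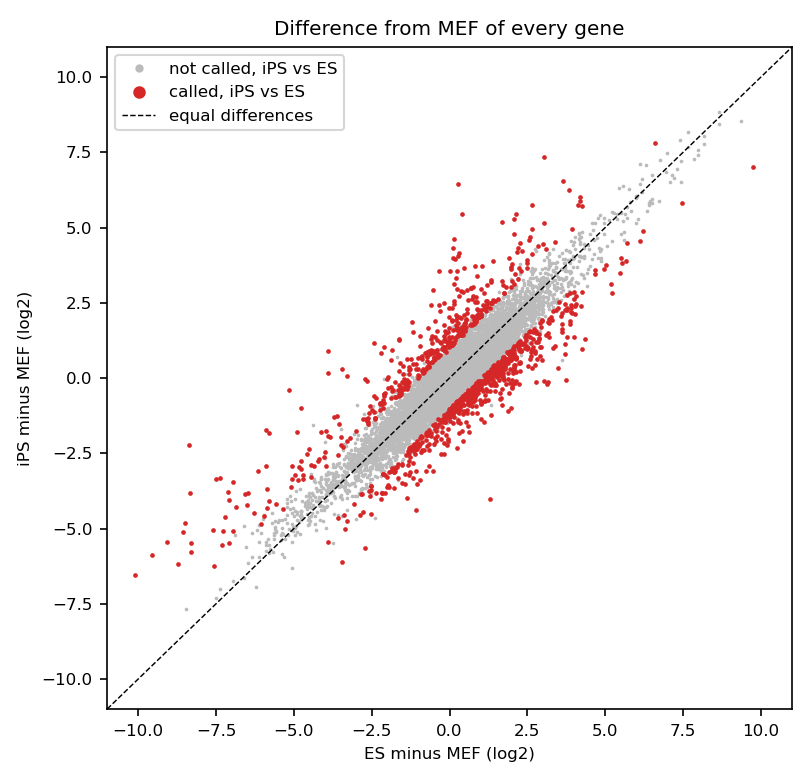
Each point is 1 of 18193 genes, with its ES minus MEF difference (log2) on the horizontal and its iPS minus MEF difference (log2) on the vertical axis, red where iPS and ES differed. The 1026 red genes lie off the dashed line of equal differences, and 10 genes were called in opposite directions against MEF.

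The next comparison asked how far the iPS lines were from ES cells. The core pluripotency factors did not pass the test, at -0.10 ± 0.12 for Pou5f1 (adjusted p = 0.656), -0.23 ± 0.19 for Sox2 (adjusted p = 0.505) and -0.23 ± 0.24 for Nanog (adjusted p = 0.612). Several other genes differed strongly. Rhox6, an X-linked homeobox gene of the germ line and placenta, was higher in iPS by 6.16 ± 0.26 (adjusted p = 0.000181), the imprinted gene Plagl1 by 6.15 ± 0.52 (adjusted p = 0.0011), Dppa3 (Stella), a maternal factor of germ cells and early embryos, by 5.06 ± 0.18 (adjusted p = 0.000181), Bola3 by 4.74 ± 0.21 and the serine protease gene Prss23 by 4.52 ± 0.43. Rhox6 and Dppa3 were at 10.81 ± 0.36 and 10.22 ± 0.20 (SD, n = 4) in iPS cells, at 4.65 ± 0.57 and 5.16 ± 0.11 (n = 2) in ES cells and at 4.37 ± 0.08 and 4.76 ± 0.33 (n = 2) in MEF. Plagl1, Bola3 and Prss23 averaged 12.55, 9.46 and 11.40 in MEF, above their iPS means of 10.34, 9.06 and 7.58. The other probe sets of Bola3, dim on all arrays, gave iPS minus ES differences of 0.11 and 0.23.

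The lowest in iPS against ES was Eif2s3y at -5.31 ± 0.25 (adjusted p = 0.000212), with iPS lines at 3.31 ± 0.21 (SD). It was followed by Rbm45 at -3.81 ± 0.13, Aspa at -3.31 ± 0.18, the homeobox gene Meis2 at -3.29 ± 0.31 and Mid1 at -3.28 ± 0.35. In MEF, Rbm45 and Aspa had means of 5.38 and 4.72, near the iPS means of 5.31 and 4.53. In all, 1026 genes were called, 437 higher and 589 lower in iPS, of which 47 and 9 by at least 8-fold. With each array's median subtracted the larger side turned, to 554 higher and 470 lower. Without R1 664 genes were called, 283 higher and 381 lower, of which 553 were among the 1026. Of the other bright probe sets of called genes 95.5% had the sign of the one used, and 5 were at least 2-fold the other way.

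Of 36 pluripotency genes 5 were lower and 2 higher in iPS than in ES (median -0.23, camera adjusted p = 0.176). Zfp42 was lower at -2.75 ± 0.12 (adjusted p = 0.000189) and Gbx2 at -1.92 ± 0.25 (adjusted p = 0.00432). Of the reprogramming factors 0 of 4 were called (adjusted p = 0.418), with Klf4 at -0.99 ± 0.27 (adjusted p = 0.0538) and Myc at -0.13 ± 0.48 (adjusted p = 0.905). The other probe set of Klf4 passed both thresholds at -1.41 ± 0.25 (adjusted p = 0.0128 over all probe sets). Thy1 was at -1.20 ± 0.36 (adjusted p = 0.0683) and was called without either MEF array (adjusted p = 0.00954). Cdh1 was at 0.51 ± 0.11 (adjusted p = 0.0264), below the fold minimum. Xist was at -0.32 ± 0.34 (adjusted p = 0.624), but its probe sets disagreed, and another gave means of 6.01 ± 0.84 in iPS, 3.85 ± 0.02 in ES and 10.38 ± 0.50 in MEF (SD). Meg3 was at -0.83 ± 0.33 (adjusted p = 0.151). Its other probe sets were also lower in iPS, none by the fold minimum. Some had an adjusted p under 0.05, with the lowest at -0.72 ± 0.15 (limma adjusted p = 0.0238 over all probe sets).

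Epithelial genes were higher in iPS than in ES, 11 of 21 and 0 lower, or 12 adjusted over the list alone (median 1.30, camera adjusted p = 6.16e-09, and adjusted p = 0.0981 with an estimated correlation). The tight junction genes Cldn7 and Cldn6 were higher by 3.33 ± 0.17 and 2.49 ± 0.18 and Esrp1 by 3.11 ± 0.20. Of 8 genes of the 2-cell embryo 4 were higher (median 1.35, adjusted p = 0.000165, and adjusted p = 0.677 with an estimated correlation), among them Pramel7 at 3.90 ± 0.64, Pramel6 at 3.22 ± 0.54 and Tcstv1 at 3.14 ± 0.48. Each of these 3 genes lost its call without CGR8 (adjusted p = 0.0536 to 0.0635) or R1 (adjusted p = 0.0608 to 0.0824). Of 14 trophectoderm genes 5 were higher (median 0.71, adjusted p = 0.000185, and adjusted p = 0.5 with an estimated correlation), with the growth factor receptor gene Fgfr2 up by 2.54 ± 0.24. Of the 3 members with the largest differences, Fgfr2 and Gata3 were as high in MEF (8.32 and 6.00) as in iPS (8.20 and 6.05). Krt7 averaged 6.09 in MEF and 7.66 in iPS. Gata3 lost its call without CGR8, R1 or S53C1, and Krt7 without any 1 of the ES or iPS arrays.

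Some serum response and fibroblast genes were also above ES. Of 27 serum response genes 11 were higher and 0 lower (median 1.03, camera adjusted p = 5.14e-06, and adjusted p = 0.792 with an estimated correlation), with Ccn1, a matricellular gene, up by 3.11 ± 0.30. Thbs1 was higher by 4.14 ± 0.81 (adjusted p = 0.0168), but was not called without CGR8, R1, S2C12 or S53C5 (adjusted p = 0.0968, 0.112, 0.0545 and 0.0562). Of 35 fibroblast genes 11 were higher and 4 lower, or 12 and 5 adjusted over the list alone (median 0.19, mean 0.72, adjusted p = 0.0499, and adjusted p = 0.882 with an estimated correlation). The call of this list was lost without CGR8 (adjusted p = 0.0621), R1 (adjusted p = 0.101), S2C12 (adjusted p = 0.0636) or S53C5 (adjusted p = 0.120) and with quantile normalisation. The matrix genes Bgn and Col5a2 were higher by 3.68 ± 0.40 and 3.63 ± 0.38 and Cdh11 by 3.67 ± 0.39, and all 3 stayed far below their MEF means of 13.73, 13.25 and 12.57. Pdgfrb, a growth factor receptor of mesenchymal cells, was lower at -2.67 ± 0.40, and was not called without R1 (adjusted p = 0.0565).

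Of 30 imprinted genes 7 were higher and 1 lower in iPS than in ES (median 0.18, adjusted p = 0.0203, and adjusted p = 0.833 with an estimated correlation). Besides Plagl1, Igf2 was higher by 2.18 ± 0.22 (adjusted p = 0.00203). Of 17 cholesterol synthesis genes 3 were higher, or 4 adjusted over the list alone (median 0.71, or 1.10 without CGR8, adjusted p = 0.000189, and adjusted p = 0.833 with an estimated correlation), but the list was not called without R1 (median 0.35, adjusted p = 0.108). The 3 called members also lost their calls without R1, with Nsdhl at 0.96, Sc5d at 0.89 and Insig1 at 0.55, all below the fold minimum. Insig1 also lost its call without any 1 of the 4 iPS lines (0.996 to 1.18). Sc5d lost its call without S2C12, S2C16 or S53C1 as well (1.31 to 1.39). Of 25 Myc targets 0 were called, and the list was higher (median 0.28, or 0.48 without CGR8, adjusted p = 0.000606, and adjusted p = 0.833 with an estimated correlation), but not without R1 (median 0.13, adjusted p = 0.108).

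Lists not called in iPS against ES were formative or primed epiblast (1 of 15 higher and 1, Otx2, lower at -1.51 ± 0.14, adjusted p = 0.836), primitive endoderm (1 of 19 lower, adjusted p = 0.836), mesoderm (1 of 13 lower, adjusted p = 0.506), neural (1 of 14, Ncam1, lower at -1.93 ± 0.22, adjusted p = 0.836), germ line (2 of 18 higher and 1, Sycp3, lower at -1.35 ± 0.16, adjusted p = 0.506), macrophage (1 of 13 lower, adjusted p = 0.836), endothelial (1 of 12 lower, adjusted p = 0.836), skeletal muscle (1 of 13 higher, adjusted p = 0.616) and adipocyte (1 of 7, the lipase gene Lpl, lower at -2.24 ± 0.21, adjusted p = 0.836). The others were Hox (3 of 33 lower, adjusted p = 0.836), DNA methylation and chromatin (Ezh2 higher by 1.15 ± 0.11 and Tet2 lower at -1.52 ± 0.20 of 22, adjusted p = 0.745), cell cycle (1 of 28, Mad2l1, higher by 1.28 ± 0.13, adjusted p = 0.174), senescence and arrest (1 of 17 higher and 1 lower, adjusted p = 0.836), glycolysis (0 of 16, adjusted p = 0.195), interferon response (1 of 21 higher, adjusted p = 0.745), antigen presentation (1 of 10 higher, adjusted p = 0.711), oxidative stress and metal response (2 of 12 higher, or 3 adjusted over the list alone, adjusted p = 0.174) and sex-linked genes (1 of 6 lower, adjusted p = 0.324). Median, mean and test differed in sign in the formative, primitive endoderm, neural, macrophage, endothelial and adipocyte lists.

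**Figure D3:**
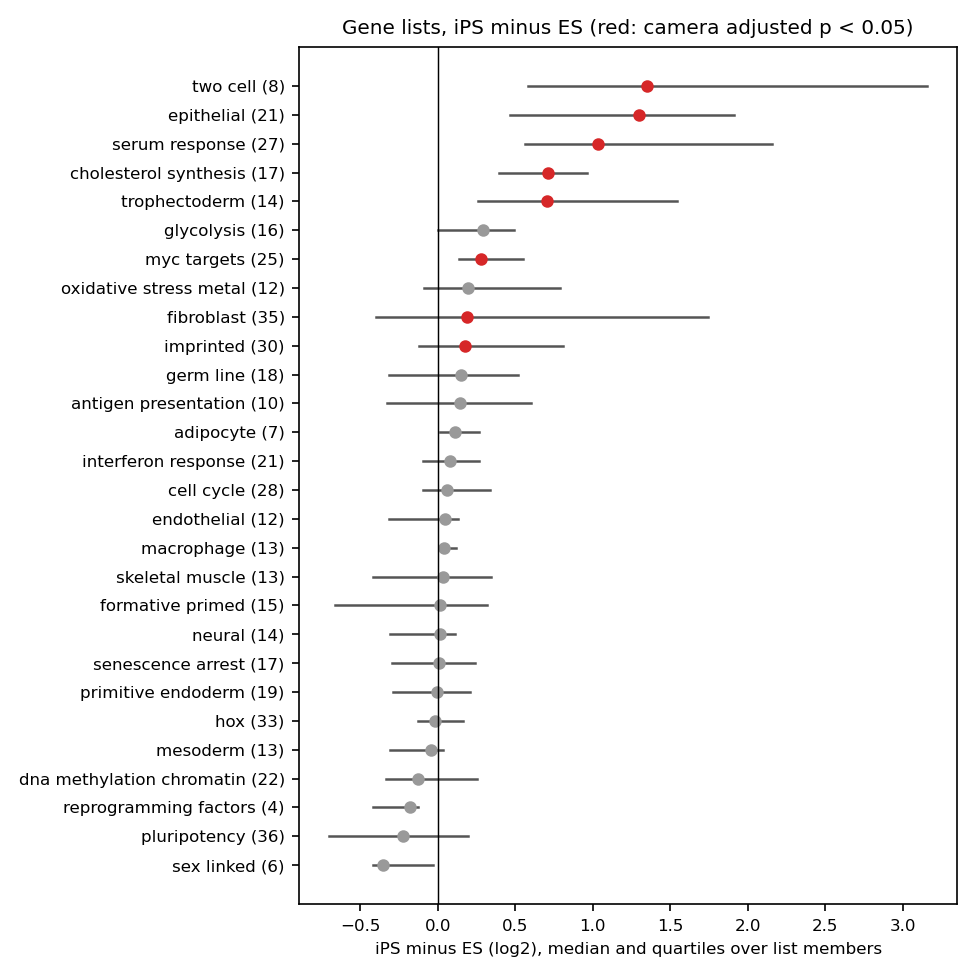
Median iPS minus ES difference (log2, point) and quartiles (line) over the measured members of the 28 gene lists, red where camera gave an adjusted p under 0.05. The 2-cell list has the highest median, 1.35, followed by the epithelial list at 1.30 and the serum response list at 1.03.

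Of the 1026 genes called between iPS and ES, 68.2% had a MEF mean on the same side of ES as iPS, 58.1% of the higher and 75.7% of the lower genes. MEF differed from ES by a call on the same side for 483 genes, against 141.2 for independent lists, and on the other side for 150, against 136.6. For 393 genes MEF and ES did not differ by a call. Both contrasts share the ES arrays, so part of this may come from them. With the ES arrays split, also chosen after the data were seen, the share was 69.0% of 664 genes with CGR8 for iPS and R1 for MEF, and 63.5% of 924 genes the other way round, with covariances of 0.20 and 0.16. In simulations without effects the share was 91.5% over the 1000 strongest genes, against 69.5% observed, and the covariance was 0.0263 against 0.203 observed. In these simulations ES and MEF do not differ, so the noise of the shared ES arrays largely sets the side. In the data ES and MEF differ in many genes, so the 91.5% does not show what share the shared arrays would give.

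The 3F and 4F lines were compared to see whether lines made without c-Myc differ. With limma 0 of 18193 genes were called (lowest adjusted p = 0.277), and 758 genes had an unadjusted p under 0.05. Without either MEF array 1 gene was called, Cap1, lower at -2.11 (adjusted p = 0.00391), which was picked out after its values were seen. Zfp352, a gene of the 2-cell list, was at -1.17 ± 0.13 (adjusted p = 0.277). Myc was at -0.80 ± 0.55, Pou5f1 at -0.25 ± 0.14, Sox2 at 0.08 ± 0.22, Klf4 at -0.14 ± 0.31, the early response gene Fos at 1.28 ± 0.30, Col1a1 at 1.12 ± 0.40 and Lefty1 at 0.90 ± 0.23, with adjusted p above 0.05 in each case.

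Camera called 7 lists between 3F and 4F lines, each with 0 called members, and none with an estimated correlation or with fry (lowest fry adjusted p = 0.371). The 2-cell list was lower in 3F lines (median -1.41, adjusted p = 6.75e-06, and adjusted p = 0.573 with an estimated correlation), with 4 of 8 members lower adjusted over the list alone, and its median was -0.65 without S53C5. Germ line genes were lower (median -0.45, adjusted p = 0.000154, and adjusted p = 0.573 with an estimated correlation), with a median of -0.20 without S53C5. The fibroblast list was higher (median 0.52, adjusted p = 5.24e-11, and adjusted p = 0.573 with an estimated correlation), with 0.18 without S2C16 and 0.28 without S53C5. A set of 85 genes far lower in ES than in MEF, and low in ES, was chosen after the data were seen. Among the 4 iPS lines, 62 of these 85 genes were lowest in S2C16 and 58 were highest in S53C5. The serum response list was higher (median 0.46, adjusted p = 5.77e-07, and adjusted p = 0.694 with an estimated correlation), with 0.18 without S2C16. Glycolysis genes were higher (median 0.20, adjusted p = 0.000148, and adjusted p = 0.694 with an estimated correlation), with 0.13 without S53C5. Epithelial genes were higher (median 0.13, adjusted p = 0.0206, and adjusted p = 0.573 with an estimated correlation) but not without S2C16 (adjusted p = 0.112) or S53C1 (adjusted p = 0.459). Chromatin genes were lower (median -0.15, adjusted p = 0.0395, and adjusted p = 0.693 with an estimated correlation) but not without S2C12, S2C16 or S53C5 (adjusted p = 0.0614, 0.112 and 0.283). The other 21 lists were not called, and median, mean and test differed in sign in the neural, cell cycle, oxidative stress and sex-linked lists.

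**Figure D4:**
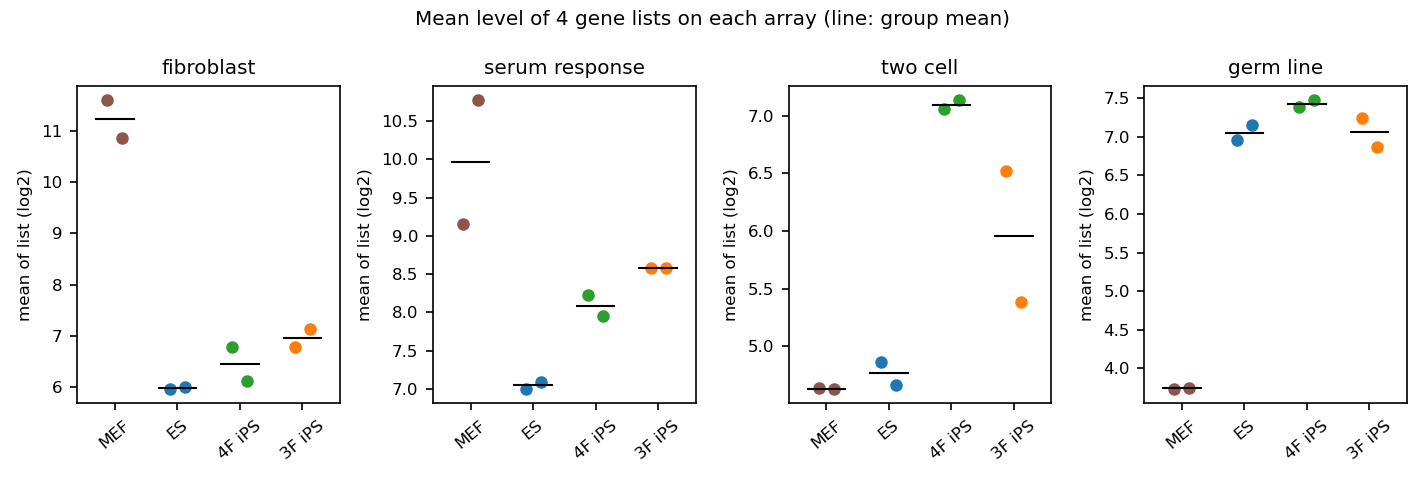
Mean log2 level of the fibroblast, serum response, 2-cell and germ line lists on each array (points, with the group mean as a line). The fibroblast list means of S2C12, S2C16, S53C1 and S53C5 were 6.78, 6.12, 6.78 and 7.12, and the 2-cell means 7.06, 7.13, 6.52 and 5.39.

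Between the MEF media, with 1 array each and no replicate check, 1276 genes differed by at least 2-fold, 625 higher and 651 lower in serum. The smooth muscle genes Cnn1 and Actg2 were higher in serum by 5.47 and 4.90, and Gjb2, Ccn5 and Acta1 by 4.75, 4.34 and 4.04. Egfl6 was lower at -6.88, the Wnt modulator gene Sfrp2 at -5.06, Kitl at -4.74, Angptl4 at -4.74 and Nrk at -4.66. The serum response and glycolysis lists had medians of 1.48 and 0.86, each above all of the 10000 random lists (percentile 100), and the interferon list a median of -1.60, below all of them (percentile 0), with Oasl2 at -4.80 and Iigp1 at -4.24. The imprinted list stood at -0.57 (percentile 0), with Cdkn1c at -3.84 and Dlk1 at -3.60. The fibroblast list had a median of -0.03 (percentile 21.8), but 10 of its 35 genes were at least 2-fold lower in serum and 1 higher. The matrix proteoglycan genes Lum and Dcn were at -5.57 and -4.66. Myc was higher in serum by 1.85.

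Between the ES lines, also 1 array each with no replicate check, 167 genes differed by at least 2-fold, 118 higher and 49 lower in R1 than in CGR8. Chac1 was higher in R1 by 3.65, Nupr1 by 2.59, Aldh1l2 by 2.55, Herpud1 by 2.06 and Vldlr by 1.95, the first 4 of them known as stress response genes. Rhox5 was lower at -2.11, Zfp365 at -1.58, Prmt8 at -1.55, Ccdc3 at -1.54 and the sterol synthesis gene Idi1 at -1.48. The cholesterol synthesis list had a median of -0.82 (percentile 0), with Lss at -1.17, and the Myc target and senescence lists -0.30 and -0.40 (percentile 0 each). The pluripotency list had a median of 0.04 (percentile 89.0).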

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

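The tests of 2 active X chromosomes, of strain and of admixed fibroblasts were chosen only after the results were seen. For 193 quantities, each iPS line was compared with the other 3 lines, and in 10 of them (5.18%) 1 line lay far from the others. Chance gives about 1 in 20 such groups, so this number is near the one chance gives. The line was S2C16 in 3, S53C1 in 3 and S53C5 in 4 of them.

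In S2C16 the mean of the senescence and arrest list was 8.10 (8.28 to 8.32 in the other lines), that of the Myc targets 11.18 (11.04 to 11.06), and Acta2 was at 8.67 (10.05 to 10.11). In S53C1 the median over all probe sets was 5.64 (5.63 to 5.64), Eomes was at 7.23 (7.02 to 7.04) and Krt7 at 8.18 (7.45 to 7.54). In S53C5 the mean of the oxidative stress list was 9.66 (9.70 to 9.71), that of the sex-linked list 4.66 (4.76 to 4.78), Cdh1 was at 11.45 (11.20 to 11.23) and Dkc1 at 11.88 (11.46 to 11.52).

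The 3F and 4F lines differed in 7 lists by a camera test of the difference between them. The medians of 3F minus 4F were -1.41 for the 2-cell, 0.52 for the fibroblast, 0.13 for the epithelial, -0.45 for the germ line, -0.15 for the chromatin, 0.20 for the glycolysis and 0.46 for the serum response list. None of the 7 passed with an estimated correlation between genes (adjusted p = 0.573 to 0.694) or with fry (adjusted p of 0.371 or more). Without S53C5 the medians of the 2-cell, germ line, fibroblast and glycolysis lists were -0.65, -0.20, 0.28 and 0.13, and without S2C16 those of the fibroblast and serum response lists were both 0.18. The epithelial list was not called without S2C16 or S53C1 (adjusted p = 0.112 and 0.459), nor the chromatin list without S2C12, S2C16 or S53C5 (adjusted p = 0.0614, 0.112 and 0.283).

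A signal was also present in the 10092 probe sets that name no single gene, which none of the comparisons between genes used. Of these, 1314 passed the same thresholds in iPS against MEF (718 higher and 596 lower), 1239 in ES against MEF (692 and 547) and 359 in iPS against ES (198 and 161).

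X-linked genes were higher in the 4 iPS lines than in ES cells, by a median of 0.69 over 285 expressed genes relative to autosomal genes, and higher than in MEF by 0.56. The values argue against brightness, since the median lay at percentile 100 of 10000 autosomal sets matched on level (highest 0.05), and against a strain difference shared by MEF and iPS cells, since MEF lay only 0.063 above ES. The iPS lines may carry 2 active X chromosomes where the ES lines carry 1, as all 11 blocks of 25 genes lay above 0 (0.38 to 0.85) and the lowest line stood at 0.65. The Y-linked gene Eif2s3y averaged 3.31 in iPS, 8.62 in ES and 7.32 in MEF arrays, and the labels give the sex of no sample. Why the iPS lines differ in this from the MEF arrays, and whether strain acts only in pluripotent cells, was not tested.

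Of the fibroblast and serum response genes, 22 were called higher in iPS than in ES cells, and strain cannot be told apart from this, because 0 ES arrays had the strain label of the iPS lines. Fibroblasts like those on the MEF arrays may have been mixed into the iPS cultures. Shares were set by 51 genes far lower in ES than in MEF, low in ES and alike on both MEF arrays. The shares were 1.44% of the RNA in S2C12, 0.648% in S2C16, 1.48% in S53C1 and 2.93% in S53C5. The choice did not use iPS levels, so the genes are low in ES and not known to be specific to fibroblasts. Bola3, 1 of the 51, averaged 9.46 in MEF and lay at 8.85 to 9.21 in the iPS lines. Of the levels of these 51 genes only those predicted at 7 or higher were compared, and 69.2% of 26 lay within 1 log2 unit, or 62.5% of 24 with each gene's own value left out of its prediction, neither of which settles it. The 22 genes, 8 of which also helped to set the shares, lay a median of 1.04 (SE 0.26) above the prediction. With shares from the 40 genes outside the lists the median was 1.09 (SE 0.26), 0.41 for the fibroblast and 1.61 for the serum response members. The 22 were chosen as called above ES on the same arrays, which by itself favours levels above the prediction. The SE is taken over these genes, which are not independent, and does not measure the spread between lines. Of the 22 genes, 20 had an iPS mean below MEF, but Fosb averaged 6.54 in iPS and 5.60 in MEF arrays, and Fos 10.61 and 10.48. For Fosb and Fos the shares predicted only 3.82 and 9.02, so RNA like that of the MEF arrays does not account for their levels. Whether admixed cells of another profile are the whole source of the 22 cannot be told apart from added activity of the iPS cells or incomplete loss of fibroblast expression, because the profile of any such fibroblasts was not measured.

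Relative to autosomal genes, chromosome 12 genes were higher in S53C5 than in the other 3 iPS lines, by a median of 0.45 over 308 expressed genes. On the same scale they were higher than in ES cells by 0.38, against -0.03 to -0.01 in the other lines. A few strongly changed genes were not enough for this, since 95.5% of the genes lay above the autosomal median. S53C5 may carry an extra copy of the chromosome, as 100% of the 12 blocks of 25 genes lay above 0.1 on that scale (0.31 to 0.52). The number of copies was not measured, and no other biological explanation was tested.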

How the results depend on the processing

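The counts without genes much higher in MEF, without all X- and Y-linked genes, without chromosome 6 genes, and with the MEF or ES arrays split between contrasts were chosen after seeing the data, and the other alternatives before the data were examined. No paired analysis was possible because the labels share no replicate numbers between groups. Without the fold minimum, which by construction only adds genes, 8706 genes were called in iPS against MEF (4666 higher and 4040 lower), 7913 in ES against MEF (4491 and 3422) and 2771 in iPS against ES (1105 and 1666). With array weights 4 genes were called between 3F and 4F lines, 1 higher and 3 lower, and they are named here although chosen after their values were seen: Cap1 (-2.11, adjusted p = 0.0199), Decr2 (-1.11, adjusted p = 0.0430), Zfp352 (-1.17, adjusted p = 0.0483) and Gt(ROSA)26Sor (1.46, adjusted p = 0.0382). From the 3F and 4F arrays alone 1 gene, Cap1, was called lower (adjusted p = 0.0125). The mean correlation of iPS with ES arrays was 0.923 when dim genes were left out, and with the mean of all probe sets of a gene 109 genes differed between R1 and CGR8. Xist turned from lower to higher in iPS than in ES, at 2.16 (adjusted p = 0.0292), when probe sets that can match several transcripts were left out, because another of its probe sets was then used. The cause of the other changes was not tested.

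Leaving out 1 array at a time gave 664 (without R1) to 1172 (without the serum-free MEF array) genes in iPS against ES, 283 to 509 of them higher and 381 to 663 lower. Of the 664 genes 553 were among the 1026. In 3F against 4F lines it gave 0 to 1, lower in 0 to 1, and the 1 gene was Cap1, without either MEF array (adjusted p = 0.00391). The share of iPS against ES genes with MEF on the same side was 65.4% (without S53C5) to 71.8% (without R1), and 71.6% without CGR8. The MEF arrays do not enter the differences of iPS minus ES or of 3F minus 4F. Leaving one of them out changed these counts only through the pooled estimate of spread, which then held no difference between the media. Apart from this and the smaller number of arrays, the cause of these changes was not tested. The counts stayed within 1.5 times in iPS against MEF (4770 to 5388), in ES against MEF (4618 to 5316) and for the genes on the same side of MEF in both (3532 to 4265), and the correlation of iPS with ES was 0.967 to 0.971. Where a group was left with 1 array, that lone sample is assumed to vary like the other groups.

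With R1 for iPS and CGR8 for MEF, the share with MEF on the same side of ES was 63.5%, against 69.0% the other way round. The cause was not tested. With the MEF arrays split, 3484 and 3606 genes lay on the same side of MEF in both contrasts. In iPS against ES the other counts stayed within 1.5 times. They were 885 without genes at least 4-fold higher in MEF than in ES, 947 without all X- and Y-linked genes, 953 without chromosome 6 genes, 999 with quantile normalisation and 830 with the mean of all probe sets. Of the named genes, 77 comparisons of iPS with ES lost and 2 gained their call when 1 array was left out and 473 kept their side of the threshold, against 18, 1 and 749 for iPS against MEF and 22, 3 and 767 for ES against MEF. Called lists were most often lost when camera estimated the correlation between genes, 17 in iPS against MEF, 16 in ES against MEF, 8 in iPS against ES and 7 in 3F against 4F lines. With fry 1, 2, 5 and 7 were lost and 5, 6, 4 and 0 gained.

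Signal over background limits what the arrays can show. A gene near the background has a compressed difference, so a low fold there is not evidence of equal expression, and 11537 of the 18193 genes passed the filter on dim genes.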

Other observations

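No tests are reported in this part, and chromosome 6 was looked at only after its values were seen. All values of chromosome 6 and its blocks are medians relative to autosomal genes. Over 378 expressed genes of chromosome 6 the median of iPS minus ES was 0.33, and the MEF arrays lay 0.22 and 0.25 above ES. Of 15 blocks of 25 genes along the chromosome, 7 that lie side by side, from Slc35b4 to Lrig1, had iPS minus ES medians of 0.59 to 0.91. In these blocks CGR8 lay at -0.51 to -1.03 and R1 at -0.55 to -0.93 against the mean of the iPS and MEF arrays. The next block, from Kbtbd8 to Rpusd3, had an iPS minus ES median of -0.51. Among the genes of this region, Bola3 averaged 4.32 in ES, 9.06 in iPS and 9.46 in MEF arrays, and Dguok 4.30, 8.37 and 8.21.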
